A study of Streptococcus gordonii with 12 samples.

How the data were processed

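RNA sequencing was used to measure transcripts in biofilms of wild-type Streptococcus gordonii, an oral bacterium, grown on plates coated with MUC5B (a mucin of saliva) or with LDP, an abbreviation that the labels do not expand. Per the labels, cultures started in BHI broth at an OD600 of 0.1 and were kept at 37 °C under 5% CO2 for between 16 and 18 h, either static or with shear, which was applied by incubating the plates on a rocker. Each of the 4 combinations of coating and flow had 3 libraries. The labels do not say whether these came from separate cultures, so p-values measure only the spread between these samples, which may be technical. RNA was extracted with a Zymo Direct-zol kit and libraries followed Illumina TruSeq protocols, per the labels.

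The values analysed are whole-number counts per feature, as deposited by the authors in 1 table with 12 columns and 2101 features. The submitters' processing notes name FastQC, TopHat2 version 2.0.13, Subread and edgeR, with no role or order. They also name the genome build mm10, which is a mouse build, whereas the features carry locus tags with the prefix SGO_RS. The bacterial assembly, the counting settings, the use of strand and any removal of ribosomal RNA are not given in the sources used here. Without strand information, reads from a gene and an antisense or overlapping partner cannot be told apart, and reads shared between near-identical copies could have been split or dropped. Columns were matched to libraries through the library number in each title, and 0 columns were left unmatched.

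Gene names were taken from the table alone. It gives a symbol for 60 features and a locus tag alone for 2041, and it does not pair locus tags with names. No reference annotation was used here, so no coordinates are given and features encoding ribosomal or transfer RNA were not identified. For the same reason 0 of the 24 adhesin, metabolic and regulatory genes chosen in advance could be reported. Of the 32 gene lists fixed in advance, 22 had 0 members under a symbol, 8 had 1 or 2 tested members, and 2 had at least 3: ribosomal proteins (8 members) and aminoacyl-tRNA synthetases (5 members). List members were recognised by symbol alone. Any known only by a locus tag were not counted and stayed among the features each list was set against. Results for the 2 lists therefore concern their symbol-bearing members, not the whole classes.

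Total counts ranged from 211530 to 492161 per library. The 6 features that each took over 2% of all counts are called dominating features below, and all 6 stayed in the main test. Of the 2101 features, 2065 had a count in some library. After edgeR's filterByExpr, 1725 were tested and 376 were left out. Replicate pairs of each group were compared by a chi-square test of their counts. The statistic per degree of freedom ranged from 2.32 to 19.3, so no pair agreed within sampling noise and every library was counted separately.

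The choices in this paragraph were made before the data were examined. Counts were scaled by trimmed mean of M-values (TMM) factors and tested with edgeR 4.0.16 (quasi-likelihood test, all 12 libraries in 1 fit with a mean per group) in R 4.3.3, with Benjamini-Hochberg adjustment over the features tested and a threshold of 0.05. The contrasts were MUC5B against LDP in each flow condition, shear against static on each coating, the difference between the 2 coating contrasts (the interaction), and the coating contrast averaged over flow. Fold changes are therefore relative to the bulk of the tested features. Gene lists were tested with camera in limma 3.58.1 (two-sided, preset inter-gene correlation 0.01, adjusted over the 2 lists), with fry beside it. Shared effects were described by correlations across features and one-sided Fisher exact tests. Library composition was compared with exact two-sided permutation tests, which with 3 against 3 libraries cannot give a p below 0.1. The rule for named genes took, in each 2-group and averaged comparison, up to 12 features per direction with the highest or lowest log2 fold change among those past the threshold, with no overlap between the groups' replicates and a mean count of at least 20, and up to 6 per direction for the interaction. The rule also took up to 4 members with the smallest adjusted p of a list named in the text.

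Nearly all features that the rule selected carry a locus tag alone: 1 of 13 in the static coating comparison has a symbol, 0 of 24 in the coating comparison under shear, 1 of 24 in the shear comparison on MUC5B and 0 of 24 in that on LDP. At most 2 locus tags that rose and 2 that fell are printed, the first-ranked in 2 comparisons. After the values were seen, it was decided to name every feature with a symbol that passed the threshold in a 2-group comparison, whatever its count. This set is not a sample of the genome and stands for no functional theme. Standard errors (SE) of log2 fold changes are approximate, computed as the log2 fold change divided by the square root of the F statistic. Counts scaled by TMM to a common library size (CPM) are given as mean ± SD over the 3 libraries of a group. Totals are read counts without molecular identifiers, so precision from depth covers counting error only.

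The procedure was tested on simulated counts drawn with the library sizes of these libraries. Each feature had 1 mean and 1 spread for all 4 groups, apart from the changes put in. In the static coating comparison 86.6% of features changed 2-fold were recovered, in the coating comparison under shear 74.6%, in the shear comparison on MUC5B 83.1% and in that on LDP 54.5%. The matching shares for 1.5-fold changes were 30.8%, 26.9%, 43.3% and 15.2%. False calls made up 5.33%, 1.50%, 2.67% and 1.82% of the calls in the same order. The real groups differed in spread, with a chi-square per degree of freedom of 2.32 to 4.76 in MUC5B static and 4.00 to 19.3 in LDP with shear. The simulated shares may therefore not hold for these data, above all where LDP with shear is compared.

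Each result was recomputed with relative log expression (RLE) factors, upper-quartile factors, library size without composition factors, no low-count filter, DESeq2 1.42.0, limma-voom, a fit of only the 2 groups compared, the replicate number as a block, a 2-fold minimum, each library left out in turn and, for gene lists, an estimated inter-gene correlation. After the data were seen, 3 more were added: the dominating features left out, limma-voom with sample quality weights, and thinning of the 6 compared libraries to 1 total outside the dominating features. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No gene order from a reference was used here, so runs of consecutive locus tag numbers are given only as an observation.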

Results

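The transcriptional profile of Streptococcus gordonii biofilms on a salivary mucin was examined in 12 RNA-seq libraries. Biofilms were grown on MUC5B-coated or LDP-coated plates, static or with shear on a rocker, with 3 libraries in each of the 4 groups. Total counts were 437075 ± 54807 for MUC5B static, 382863 ± 42663 for LDP static, 344194 ± 44006 for MUC5B with shear and 274394 ± 55635 for LDP with shear (SD, n = 3). A group of 6 dominating features, each known only by a locus tag, took 31.7% ± 2.85 of the counts in MUC5B static, 37.5% ± 14.4 in LDP static, 45.9% ± 9.65 in MUC5B with shear and 69.9% ± 16.2 in LDP with shear (SD, n = 3). Their share was higher with shear than without on each coating, with no overlap between the 3 shear and the 3 static libraries (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). It did not separate the coatings (exact permutation p = 0.7 static and 0.2 with shear). LDP with shear replicate 3 had only 30168 counts outside these features and a median count of 8 per tested feature, against 28 and 21 in the other libraries of its group.

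**Figure D1:**
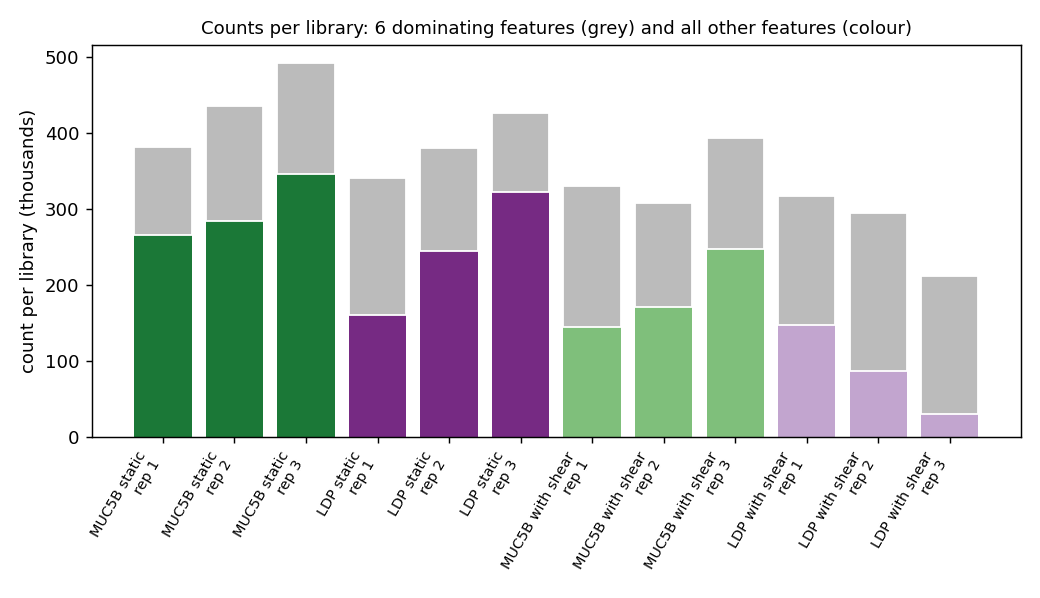
Total count of each of the 12 libraries (bars), split into the 6 dominating features (grey) and all other features (coloured by group). The counts outside the dominating features ranged from 30168 in LDP with shear replicate 3 to 346619 in MUC5B static replicate 3.

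To investigate how the mucin coating alone related to gene expression, MUC5B and LDP biofilms were first compared without shear. Of the 58 tested features with a symbol, 1 passed edgeR's threshold (0 with DESeq2, 1 with limma-voom): glpK, which encodes glycerol kinase, was 2.67-fold higher on MUC5B (246 ± 18.3 against 90.8 ± 55.8 CPM, SD, n = 3; log2 fold change 1.42, SE 0.30, edgeR adjusted p = 0.026). All 3 MUC5B libraries lay above all 3 LDP libraries, which is no added evidence for a gene called on these same libraries. Among features without a symbol, SGO_RS07445 rose most on MUC5B by the naming rule, 4.30-fold (132 ± 9.60 against 29.0 ± 23.5 CPM; log2 fold change 2.10, SE 0.30, edgeR adjusted p = 0.00126). SGO_RS09930 fell most, with 102 ± 6.91 CPM on MUC5B against 240 ± 32.9 on LDP (log2 fold change -1.23, SE 0.16, edgeR adjusted p = 0.000751). Of the genes that did not pass, agaS had a log2 fold change of 1.53 (SE 0.43, edgeR adjusted p = 0.163, mean count 10.4; 2.48 and 0.0108 without LDP static replicate 2), and rpsA, which encodes ribosomal protein S1, had 0.56 (SE 0.16, edgeR adjusted p = 0.159). For the ribosomal proteins 0 of 8 members passed in edgeR's test (2 at an unadjusted p under 0.05, 0 with DESeq2 or limma-voom), 1 was higher when adjusted over the list alone, and the list did not stand apart (camera adjusted p = 0.438). For the aminoacyl-tRNA synthetases 0 of 5 passed (1 unadjusted, 0 with DESeq2 or limma-voom), also when adjusted over the list alone (camera adjusted p = 0.438).

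In all, 14 of 1725 features differed between the coatings without shear in edgeR's test, 10 higher and 4 lower on MUC5B, and 185 had an unadjusted p under 0.05. The call of glpK was lost with DESeq2 (adjusted p = 0.155, within a range of 4.07e-05 to 0.326 over all alternatives) and on leaving out MUC5B static replicate 1 (0.129), 2 (0.102) or 3 (0.118) or LDP static replicate 1 (0.153) or 3 (0.326). Without LDP static replicate 2 the log2 fold change was 2.08 for glpK and 2.89 for SGO_RS07445. The count was 56 without that library, 5 without LDP static replicate 3, 7 without LDP static replicate 1, and 7, 6 and 7 without MUC5B static replicates 1, 2 and 3. With library size only it was 7, all higher on MUC5B.

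The same comparison under shear addressed the coating difference in biofilms grown on the rocker. celB, whose name denotes a sugar-transport component of a cellobiose phosphotransferase system, was 1.75-fold higher on MUC5B (496 ± 22.4 against 264 ± 88.1 CPM, SD, n = 3; log2 fold change 0.81, SE 0.19, edgeR adjusted p = 0.0296), and was the 1 feature with a symbol that passed in edgeR's test (3 with DESeq2, 1 with limma-voom). Its libraries did not overlap between the coatings, which is no added evidence for a gene called on them. SGO_RS04020 was also higher on MUC5B under shear (973 ± 210 against 413 ± 159 CPM; log2 fold change 1.15, SE 0.23, edgeR adjusted p = 0.0281). The ribosomal protein gene rpmI (log2 fold change 0.93, SE 0.27, edgeR adjusted p = 0.0608), recX, which encodes a regulator of the RecA recombinase (-0.79, SE 0.23, edgeR adjusted p = 0.0597), and glyA, which encodes serine hydroxymethyltransferase (-0.67, SE 0.20, edgeR adjusted p = 0.0636), did not pass. Leaving out MUC5B with shear replicate 3 brought rpmI past the threshold (adjusted p = 0.0457), and leaving out LDP with shear replicate 1 did so for recX (0.0494) and glyA (0.00947). Of the ribosomal proteins 0 of 8 passed in edgeR's test (3 at an unadjusted p under 0.05, 0 with DESeq2 or limma-voom), and 1 was higher when adjusted over the list alone (camera adjusted p = 0.194). Of the aminoacyl-tRNA synthetases 0 of 5 passed (1 unadjusted, 0 with DESeq2 or limma-voom), also when adjusted over the list alone (camera adjusted p = 0.194). The dominating features took 45.9% of counts on MUC5B and 69.9% on LDP in these libraries. A dominating feature was itself among those called lower on MUC5B (log2 fold change -2.56, SE 0.62, edgeR adjusted p = 0.0354).

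In all, 76 features differed, 42 higher and 34 lower on MUC5B, and 376 had an unadjusted p under 0.05. DESeq2 gave 125, of which 54 were higher and 71 lower. Library size only gave 1022 higher and 2 lower, a scaling in which the median log2 fold change of all tested features was itself 1.04. The count was 0 in a fit of the 6 shear libraries alone (263 at an unadjusted p under 0.05). It was 2, 0, 24, 158, 0 and 42 on leaving out MUC5B with shear replicates 1, 2 and 3 and LDP with shear replicates 1, 2 and 3. celB did not pass without MUC5B with shear replicate 1, 2 or 3 (adjusted p 0.0557, 0.105 and 0.0569) or LDP with shear replicate 2 (0.122), nor in the fit of the shear libraries alone (0.126) or that fit after thinning to 1 total (0.160), within a range of 0.00203 to 0.160 over all alternatives. SGO_RS04020 did not pass without MUC5B with shear replicate 1 (0.0547) or 2 (0.0717) or LDP with shear replicate 2 (0.0892), nor in the fit of the shear libraries alone (0.122, and 0.110 after thinning).

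**Figure D2:**
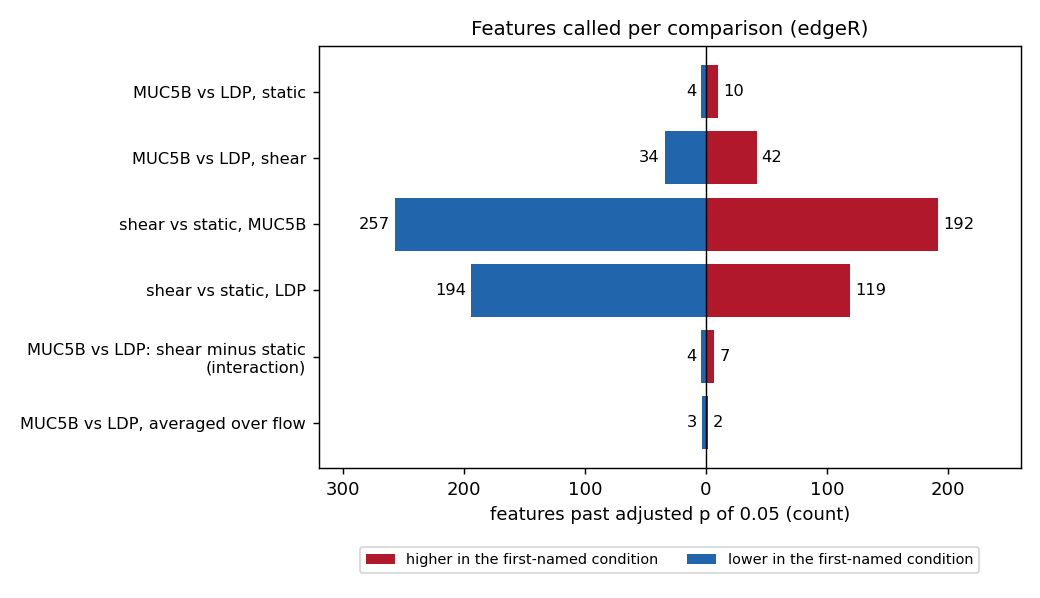
Number of features past an adjusted p of 0.05 in each comparison, with those higher in the first-named condition to the right and those lower to the left. The shear comparisons gave 449 and 313 features and the coating comparisons 14 and 76.

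To examine the effect of shear on the mucin surface, MUC5B biofilms with and without shear were compared. pflA, which encodes the activating enzyme of pyruvate formate-lyase, fell 3.68-fold (764 ± 59.1 to 204 ± 61.9 CPM, SD, n = 3; log2 fold change -1.88, SE 0.20, edgeR adjusted p = 3.69e-06). glgC, which encodes the ADP-glucose-forming enzyme of glycogen synthesis, fell 4.20-fold (2935 ± 234 to 699 ± 86.2 CPM; -2.07, SE 0.25, edgeR adjusted p = 1.13e-05). glpK fell 7.48-fold (246 ± 18.3 to 31.9 ± 5.10 CPM; -2.90, SE 0.36, edgeR adjusted p = 1.52e-05). agaS fell 8.72-fold at low counts (51.6 ± 8.56 to 6.43 ± 7.30 CPM; -3.12, SE 0.57, and -4.39 without MUC5B with shear replicate 1). Also lower were pheS, which encodes a subunit of phenylalanyl-tRNA synthetase (-1.46, SE 0.27), the DNA ligase gene ligA (-1.04, SE 0.19), the alcohol dehydrogenase gene adhP (-0.86, SE 0.19), the recombinase gene xerS (-0.78, SE 0.17), the GTPase gene obgE (-0.56, SE 0.19) and celB (-0.45, SE 0.16). All 17 symbol-bearing features that passed in edgeR's test (15 with DESeq2, 16 with limma-voom), 10 lower and 7 higher, had no overlap between the 3 shear and the 3 static libraries. They were called on these same libraries, so the separation is no added evidence. Chance gives it to 10% of features that were not selected.

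Of the 8 ribosomal protein genes with a symbol, 4 were higher with shear on MUC5B and 4 did not pass, with the same numbers when adjusted over the list alone (camera adjusted p = 0.0388, upward). The median log2 fold change of the list was 0.36, and 0.19 with library size only, a scaling that also moved the median of all tested features downward. The list's call was lost when the inter-gene correlation was estimated (adjusted p = 0.153 with an estimated correlation), and fry, which asks whether the members move on balance in 1 direction, gave p = 0.00239. rpmI rose 2.01-fold (71.8 ± 10.9 to 149 ± 37.0 CPM; log2 fold change 1.01, SE 0.21, edgeR adjusted p = 0.00161). On the log2 scale rpsN rose by 0.87 (SE 0.22), rpsP by 0.67 (SE 0.21) and rplB by 0.47 (SE 0.17). The values of the other members were 0.24 for rpsA, 0.24 for rpmE2, -0.01 for rplL and -0.23 for rplS. Also higher were rnpA, which encodes the protein part of ribonuclease P (0.73, SE 0.18), the DNA polymerase gene dnaE (0.61, SE 0.16) and the GTPase gene engB (0.43, SE 0.14). Of the 5 aminoacyl-tRNA synthetases with a symbol only pheS passed, also when adjusted over the list alone, and the list did not stand apart (camera adjusted p = 0.666, with a median log2 fold change of 0.06 and a mean of -0.22). The dominating features took 31.7% of counts in the static and 45.9% in the shear libraries on this coating.

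In all, 449 of 1725 features (26.0%) differed with shear on MUC5B, 192 higher and 257 lower, and 147 of them changed at least 2-fold, 26 higher and 121 lower. By the naming rule SGO_RS00800 fell most, 14.6-fold (1314 ± 122 to 89.6 ± 8.76 CPM; log2 fold change -3.87, SE 0.34, edgeR adjusted p = 3.52e-07). SGO_RS04020 rose 2.50-fold (387 ± 42.3 to 973 ± 210 CPM; 1.32, SE 0.21, edgeR adjusted p = 0.000174). With library size only the count was 100, 3 higher and 97 lower. The count was 290 without MUC5B static replicate 1, 296 without MUC5B with shear replicate 1 and 290 without MUC5B with shear replicate 2, and 11 of the 17 symbol-bearing calls held on leaving out any 1 library. celB and rplB were lost without each of the 6 libraries in turn (adjusted p 0.0871 to 0.137 and 0.0559 to 0.227). engB and rpsP were lost without MUC5B static replicate 1 or 3 or MUC5B with shear replicate 1 or 2 (0.0959 to 0.131 and 0.0522 to 0.110). obgE was lost without MUC5B static replicate 1 or 2 or MUC5B with shear replicate 1 or 3 (0.0615 to 0.165), as was dnaE without MUC5B with shear replicate 1 (0.0665).

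To examine whether shear changed expression on the other coating, LDP biofilms with and without shear were compared. pflA fell 3.38-fold (638 ± 102 to 184 ± 47.7 CPM, SD, n = 3; log2 fold change -1.76, SE 0.23, edgeR adjusted p = 0.00012). glgC fell 2.37-fold (2288 ± 649 to 983 ± 306 CPM; -1.25, SE 0.25, edgeR adjusted p = 0.00437). xerS fell 2.39-fold (812 ± 66.8 to 340 ± 77.7 CPM; -1.26, SE 0.19, edgeR adjusted p = 0.000471), and celB fell 2.06-fold (580 ± 36.0 to 264 ± 88.1 CPM; -1.04, SE 0.19, edgeR adjusted p = 0.00201). pheS fell 3.30-fold (-1.72, SE 0.36, edgeR adjusted p = 0.00484). groEL, which encodes the GroEL chaperonin, fell 2.65-fold (13531 ± 1261 to 5098 ± 2582 CPM; -1.40, SE 0.38, edgeR adjusted p = 0.0188). Smaller falls were found for adhP (-0.79, SE 0.23), the glucose-6-phosphate isomerase gene pgi (-0.77, SE 0.26), ligA (-0.62, SE 0.21) and deoA, which encodes a pyrimidine-nucleoside phosphorylase (-0.56, SE 0.18). Higher with shear were glyA (0.84, SE 0.20), recX (0.79, SE 0.23) and glmM, which encodes phosphoglucosamine mutase (0.75, SE 0.19), although with library size only the log2 fold changes of these 3 were -0.22, -0.22 and -0.29. In that scaling the median of all tested features was lower still. All 13 that passed in edgeR's test (14 with DESeq2, 13 with limma-voom) separated the 3 shear from the 3 static libraries with no overlap. As on MUC5B, these features were called on the same libraries, so the separation is no added evidence.

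The ribosomal proteins had a median log2 fold change of 0.43 with shear on LDP, but 0 of 8 passed in edgeR's test (4 at an unadjusted p under 0.05, 0 with DESeq2 or limma-voom), also when adjusted over the list alone, and the list did not stand apart (camera adjusted p = 0.150). rplB, rplS, rpsA and rpsN each passed, higher with shear, on leaving out 1 of the 6 libraries. With library size only the median of the ribosomal proteins was -0.61, but in that scaling the median of all tested features was lower still. Of the 5 aminoacyl-tRNA synthetases with a symbol 1 fell and 0 rose over all features, and 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.684, upward, with a median of 0.04 and a mean of -0.15). glpK (-1.06, SE 0.53, edgeR adjusted p = 0.175) and agaS (-1.08, SE 0.91, edgeR adjusted p = 0.457) did not pass on LDP, and both values hang on single libraries. In the shallow LDP with shear replicate 3 they had 10 and 2 counts, and without that library the log2 fold changes were -1.80 (adjusted p = 0.0295) and -1.82 (0.273). Without LDP static replicate 2 they were -0.41 (0.634) and -0.12 (0.957). The dominating features took 37.5% of counts in the static and 69.9% in the shear libraries.

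In all, 313 features (18.1%) differed with shear on LDP, 119 higher and 194 lower, and 137 changed at least 2-fold, 35 higher and 102 lower. SGO_RS00800 fell 11.0-fold (792 ± 486 to 69.6 ± 9.60 CPM; log2 fold change -3.46, SE 0.40, edgeR adjusted p = 2.5e-05). With library size only 4 features were higher and 976 lower, in a scaling where the median log2 fold change of all tested features was itself -1.06. The count was 102 in a fit of the LDP libraries alone and 33 in that fit after thinning to 1 total. It was 163 and 201 without LDP static replicates 2 and 3, 119 without LDP with shear replicate 2, and 248 without the shallow LDP with shear replicate 3. deoA was lost without each of the 6 libraries (adjusted p 0.0512 to 0.0950). pgi was lost without each but LDP with shear replicate 1 (0.0640 to 0.114). ligA was lost without LDP static replicate 2 or 3 or LDP with shear replicate 2 or 3 (0.0651 to 0.147). adhP was lost without LDP static replicate 2 or LDP with shear replicate 2 or 3 (0.0586 to 0.104). recX was lost without LDP static replicate 2 or 3 or LDP with shear replicate 2 (0.0510 to 0.117). groEL was lost without LDP static replicate 3 (0.0528) or LDP with shear replicate 2 (0.0669).

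**Figure D3:**
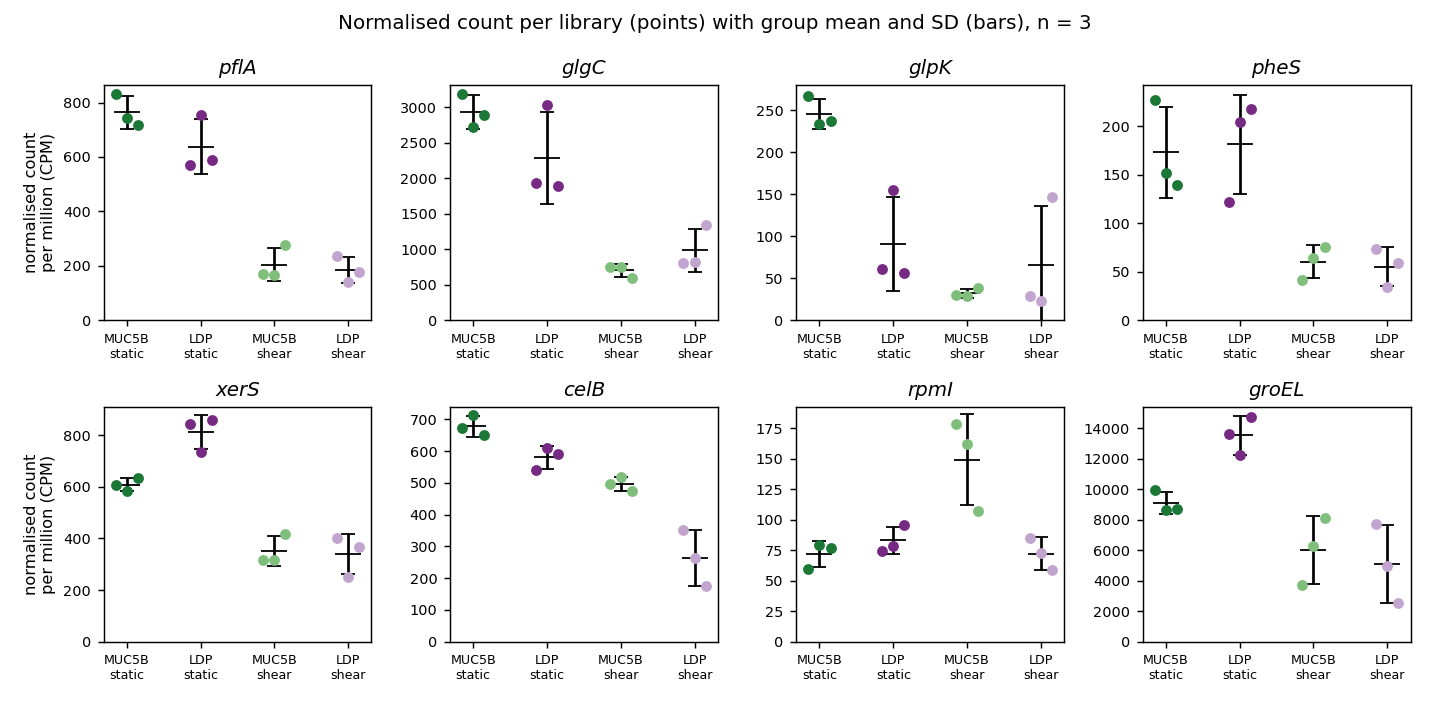
Normalised counts (CPM) of 8 genes in each library (points), with the mean and SD of each group of 3 (horizontal mark and bars). pflA, glgC, pheS and xerS were lower in the shear libraries on both coatings, and glpK was highest in MUC5B static at 246 CPM.

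The shear effects on the 2 coatings, which share no library, were then set against each other. pflA, glgC, pheS, ligA, adhP, xerS and celB passed and fell on both coatings. Across the 1725 features the log2 fold changes correlated with Pearson's r = 0.552 (Spearman's rho = 0.486), although features are not independent replicates. A total of 42 features rose on both coatings, where 13.2 would be shared by independent lists (one-sided Fisher exact p = 2.47e-13), and 120 fell on both, where 28.9 would be (one-sided Fisher exact p = 8.64e-61). Both tests treat features as independent, but features with neighbouring tag numbers changed together (r = 0.538 on MUC5B and 0.428 on LDP). The p-values therefore overstate the evidence. Of the features called in opposite directions there were 0, and 85.5% of the 600 called on either coating had the same sign on both. The correlation was 0.359 with no low-count filter.

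**Figure D4:**
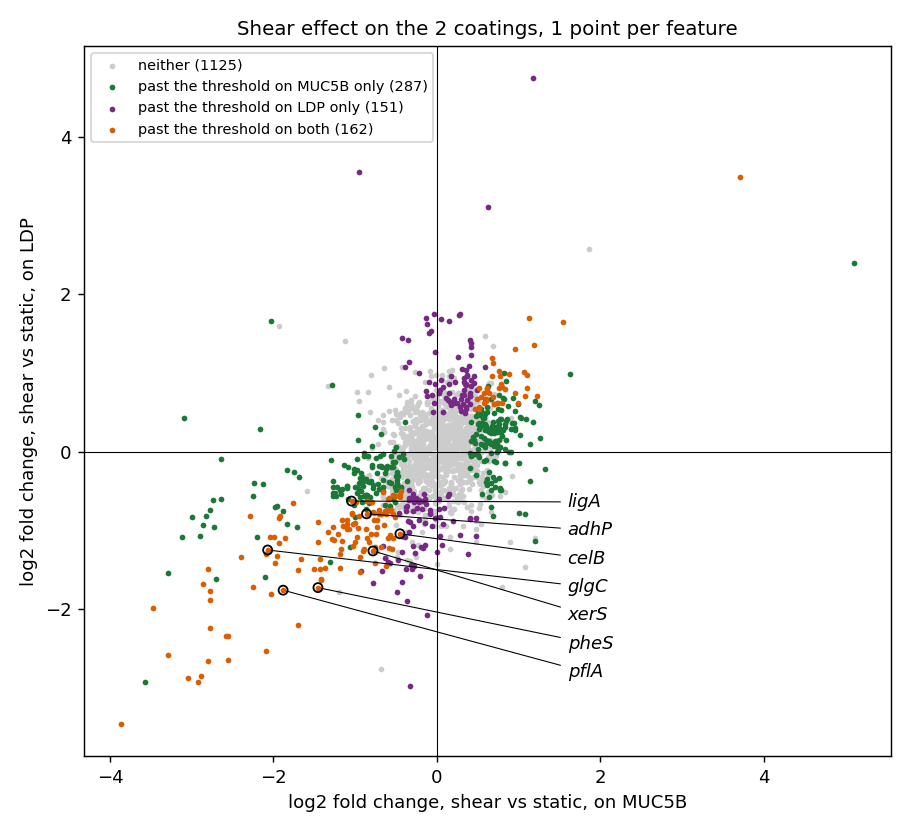
Log2 fold change of shear against static on MUC5B (horizontal) and on LDP (vertical), 1 point per tested feature, coloured by where it passed the threshold, with the symbol-bearing features that passed on both coatings circled and named. The 7 named genes lie at the lower left, among the 120 features that fell on both coatings.

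The coating effects in the 2 flow conditions were compared in the same way. Neither glpK, which passed without shear, nor celB, which passed with shear, passed in both conditions. Across features the log2 fold changes correlated with r = -0.00215 (rho = 0.0126). In edgeR's test 0 calls were shared in either direction, where 0.243 higher and 0.0788 lower would be shared by independent lists. DESeq2 and limma-voom also gave 0 shared calls. At an unadjusted p under 0.05 in edgeR's test, 8 higher and 8 lower were shared, and the number to set against these was not computed. Of the 90 features called in either condition 63.3% had the same sign in both, and 0 were called in opposite directions.

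Whether the coating effect differed between flow conditions was tested directly as an interaction. SGO_RS04020 was among the features that differed: its log2 fold change on MUC5B against LDP was -0.39 without shear (SE 0.21, not past the threshold) and 1.15 with shear, a difference of 1.53 (SE 0.31, edgeR adjusted p = 0.0289). Of the 58 features with a symbol 0 passed in edgeR's test, 11 had an unadjusted p under 0.05, and 0 passed with DESeq2 or limma-voom. The values for glpK (-1.84, SE 0.74, edgeR adjusted p = 0.216), rpmI (1.15, SE 0.35, edgeR adjusted p = 0.118), celB (0.59, SE 0.25, edgeR adjusted p = 0.236) and glgC (-0.82, SE 0.35, edgeR adjusted p = 0.239) did not pass, so their changes with shear were not shown to differ between the coatings. glpK passed without LDP static replicate 2 (-2.49, adjusted p = 0.0398) and moved to -1.12 (0.519) without LDP with shear replicate 3, and celB passed without LDP with shear replicate 1 (0.0379). Neither list stood apart, with 0 of 8 ribosomal proteins and 0 of 5 aminoacyl-tRNA synthetases past edgeR's threshold (2 and 1 at an unadjusted p under 0.05, 0 with DESeq2, and 1 and 0 when adjusted over the list alone; camera adjusted p = 0.551 for each). In all, 11 features passed, 7 higher and 4 lower, and 287 had an unadjusted p under 0.05. DESeq2 gave 41. Library size only gave 40 higher and 2 lower, in a scaling where the median of all tested features was itself 0.86. The count was 1, 1 and 3 without MUC5B static replicates 1, 2 and 3, and 1, 39 and 1 without those of LDP static. It was 7, 1 and 6 without MUC5B with shear replicates 1, 2 and 3, and 109, 2 and 21 without those of LDP with shear. SGO_RS04020 was lost without each MUC5B static library (adjusted p 0.0571 to 0.119), without LDP static replicate 1 or 3 (0.0682 and 0.105), without MUC5B with shear replicate 1 or 2 (0.0622 and 0.110) and without LDP with shear replicate 2 (0.156).

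Averaged over flow, SGO_RS09930 was lower on MUC5B (log2 fold change -0.77, SE 0.12, edgeR adjusted p = 0.0094), 1 of 5 features that passed, of which 2 were higher and 3 lower. Its value with shear was only -0.32 (SE 0.18, edgeR adjusted p = 0.329) against -1.23 without, so its average rests mostly on the static libraries, although the difference of 0.91 (SE 0.24, edgeR adjusted p = 0.0766) did not pass. The other 4 carry a locus tag alone. Each of them separated the coatings with no overlap in both flow conditions, whereas SGO_RS09930 did so only without shear. All were called on these same libraries, so the separation is no added evidence. Of the 58 features with a symbol 0 passed in edgeR's test, 8 had an unadjusted p under 0.05, 4 passed with DESeq2 and 0 with limma-voom. Neither the ribosomal proteins nor the aminoacyl-tRNA synthetases stood apart as a list (camera adjusted p = 0.125 for each), with 0 members of each past edgeR's threshold (3 and 0 at an unadjusted p under 0.05, 1 and 0 with DESeq2, and 1 and 0 when adjusted over the list alone). An unadjusted p under 0.05 was found for 312 features, and DESeq2 gave 78. Library size only gave 733 higher and 2 lower, in a scaling where the median of all tested features was itself 0.61. The count was 3, 0 and 1 without MUC5B static replicates 1, 2 and 3, and 1, 62 and 0 without those of LDP static. It was 2, 1 and 1 without MUC5B with shear replicates 1, 2 and 3, and 96, 0 and 67 without those of LDP with shear. SGO_RS09930 was lost without MUC5B static replicate 2 (adjusted p 0.0624), LDP static replicate 3 (0.0523) or LDP with shear replicate 2 (0.0695).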

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

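The tests of library order and of LDP static replicate 2 were chosen only after the results were seen. Also chosen afterwards was the comparison of LDP with shear replicate 3 with the other left-out libraries.

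The coating effect differed between static and shear libraries, by a test of the difference itself, for 11 features. For deoA the log2 fold change on MUC5B against LDP was -0.13 without shear (SE 0.15, edgeR adjusted p = 0.787) and 0.58 with shear (SE 0.18, edgeR adjusted p = 0.0649), and the tested difference was 0.70 (SE 0.23, edgeR adjusted p = 0.139). For dnaE the values were -0.18 (SE 0.16) and 0.30 (SE 0.17), with a difference of 0.48 (SE 0.23, edgeR adjusted p = 0.318). The libraries did not overlap in either condition for either gene, but without shear the nearest libraries of the 2 coatings both had 374 CPM of deoA. Neither difference passed the threshold.

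The first pattern is the shear profile, with 449 features on MUC5B and 313 on LDP and a fall of pflA and glgC on both coatings. Whether lower depth contributed could not be decided by thinning, which keeps the expected proportions of features and so nearly fixes fold changes in advance. After the 6 libraries were thinned to 1 total outside the dominating features, the median log2 fold change of the called features in their direction was 1.05 of its former value on MUC5B (95% interval 1.002 to 1.093, 429 features). It was 1.102 on LDP (1.042 to 1.193), where the test covered only 186 of the 313 features because the others fell under the count filter. The share of the dominating features could be tested only in part. A score per library, built from the features called on the other coating, differed between shear and static by 1.19 log2 units before and 1.11 (95% interval 0.696 to 1.52) after adjustment for that share. Within a coating the share did not overlap between shear and static, so the adjustment reaches beyond the data. At the nearest shares the score was -0.161 in LDP static replicate 1 (52.8%) and 0.638 in LDP with shear replicate 1 (53.4%). On MUC5B it was -1.48 in static replicate 2 (34.9%) and -0.410 in shear replicate 3 (37.0%). These single libraries differ at nearly equal share, but a part played by the share stays open. Shear itself, which the design names, stays open as untested. The labels name no batch or run, and 0 shear libraries have a number below the highest static library number, so an order of handling or sequencing could not be examined. In each 2-group comparison the 10 possible splits are too few for a share under 0.05, with 449 features for the real split (highest other 0) and 313 (highest other 1).

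The second pattern is the instability of the coating calls. For the 76 calls under shear, the shallowest library, LDP with shear replicate 3, may contribute: the count fell to 42 without it, of which 34 were among the 76. The bound set in advance was met, but leaving out other libraries gave 0 to 158, so the fall is not specific to that library and its part cannot be told apart from the loss of any replicate. The 10 splits were again too few for a share under 0.05, with 76 features for the real split (highest other 1) and 14 without shear (highest other 0). For the interaction (11 features, highest other 1) and the averaged comparison (5 features, highest other 0), only 1 of 100 regroupings of the coating labels drawn from 200, the real one, gave as many. Among these libraries this argues against chance only for a coating difference of some kind, since the regroupings mix the coatings within a flow condition. Chance differences between cultures are not covered if the libraries of a group are technical. The regroupings do not single out an interaction or an average. Exchanging the labels in the shear libraries alone, which was not drawn, gives 11 for the average and 5 for the interaction. That exchange turns 1 contrast into the other. In every fit with 1 library left out, 1 of the 11 and 0 of the 5 calls were made.

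The third pattern is that LDP static replicate 2 lies near the MUC5B static libraries. Its mean correlation of log2 CPM across features was 0.973 with those and 0.958 with the other LDP static libraries, a gap of 0.0151, and leaving it out moved the static coating count from 14 to 56. A swap with a MUC5B static library is argued against, since 0 of these lay closer to the LDP static libraries than to their own group. A single wrong label or a mixed coating may also be the reason, but 0.973 lies below the lowest mean correlation within MUC5B static, 0.978, so these tables leave it open, as they do ordinary variation between biofilms, for which no test was run. By mean correlation, LDP static replicate 2 was not the only library nearer to another group. LDP with shear replicate 1 correlated at 0.925 with LDP static and 0.904 with MUC5B static, but at 0.869 with its own group. LDP with shear replicate 2 had 0.891 with LDP static and 0.887 with its own group. Both of these own-group means include the shallow LDP with shear replicate 3 (r = 0.812 with replicate 1 and 0.847 with replicate 2). Replicates 1 and 2 correlated with each other at 0.926, above the mean of either with LDP static. Their low own-group means thus come from replicate 3, and why that library differs was not tested.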

How the results depend on the processing

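The alternatives with dominating features left out, voom quality weights and thinning were chosen after seeing the data. Counts of features past the threshold are given in the order coating static, coating with shear, shear on MUC5B, shear on LDP, interaction and averaged coating (main values 14, 76, 449, 313, 11 and 5), and a count within 1.5 times of the main one is not repeated. The cause of each move was not tested unless stated.

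With library size only the counts were 7, 1024, 100, 980, 42 and 735, since the dominating features then enter the scaling: the median log2 fold change of all tested features moved to 0.19, 1.04, -0.14, -1.06, 0.86 and 0.61, and glyA (-0.22), glmM (-0.29) and recX (-0.22) turned from higher to lower with shear on LDP. The averaged coating count moved to 18 with RLE factors, 20 with upper-quartile factors, 8 without a low-count filter, 3 with limma-voom and 13 with the dominating features left out, and the interaction count to 17 without a low-count filter. DESeq2 gave 125 for coating with shear, 41 for the interaction and 78 for the average. A fit of only the 2 groups gave 0 for coating with shear (263 unadjusted) and 102 for shear on LDP. All such fits rest on fewer libraries, but only those holding LDP with shear moved. Replicate pairs of that group correlated in log2 CPM with r = 0.812 to 0.926, against 0.977 to 0.980 in MUC5B static. The main fit shares 1 spread over all groups. The 2-fold minimum, stricter by construction, left 31 for coating with shear, 147 and 137 for shear on MUC5B and LDP, and 0 for the average (312 unadjusted). Quality weights gave 130, 139, 104 and 147 for coating static, coating with shear, interaction and average. Thinning, in such 2-group fits, gave 0 for coating with shear (117 unadjusted), as those fits did without thinning, and 33 for shear on LDP against 102 without it.

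Leaving out 1 library at a time, with fewer libraries by construction, gave 5 to 56 for coating static, 0 to 158 for coating with shear, 290 to 427 for shear on MUC5B, 119 to 390 for shear on LDP, 1 to 109 for the interaction and 0 to 96 for the average. Of the main calls, 5 of 14, 0 of 76, 227 of 449, 88 of 313, 1 of 11 and 0 of 5 were made in every such fit. The counts at an unadjusted p under 0.05 beside those zeros were 308 and 296 for coating with shear and 258 to 266 for the average. The correlation of shear effects between coatings was 0.359 without a low-count filter and 0.400 to 0.592 over left-out libraries, and that of coating effects between flow conditions was -0.07 to 0.0617. The ribosomal protein list on MUC5B had adjusted p = 0.153 with an estimated correlation and kept its call without a low-count filter (0.0259).

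For symbol-bearing features that did not pass, left-out libraries were examined after the values were seen, and moves are given beside the gene. Over all alternatives, single features were followed only where they carry a symbol or are 1 of the 4 printed locus tags, a limit set after the values were seen. Of their 42 calls, direction was kept in all alternatives except the 3 reversals above. The threshold was no longer passed by 16 with library size only, 1 with upper-quartile factors, 2 without a low-count filter, 3 with DESeq2, 1 with limma-voom and 3 with quality weights, and by 0 with RLE factors or with the dominating features left out. It was missed by 8 of 40 in fits of only the 2 groups and by 10 of 37 after thinning.

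The replicate numbers are shared between groups but did not pair the libraries: same-number correlations ran from -0.166 to 0.156, with 2 of 18 pairs over 0.1, and 4 of 12 libraries correlated best with their own number. With the replicate block the counts were 9, 0, 402, 255, 1 and 0 (342 and 285 unadjusted at the zeros), 10 of the 42 calls did not pass, among them celB and SGO_RS04020 for coating with shear (adjusted p 0.0580 each), and the ribosomal protein list on MUC5B kept its call (0.0334). Leaving out ribosomal and transfer RNA features was planned and not run, because no annotation identified them.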

Other observations

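Several abundant or widely used genes with a symbol did not pass the threshold in any 2-group comparison. dnaK, which encodes the DnaK chaperone, had 9663 ± 580 CPM in MUC5B static, 14673 ± 3066 in LDP static, 10113 ± 71.5 in MUC5B with shear and 15862 ± 6043 in LDP with shear (SD, n = 3), with log2 fold changes on MUC5B against LDP of -0.60 (SE 0.34, edgeR adjusted p = 0.536) without shear and -0.65 (SE 0.34, edgeR adjusted p = 0.281) with it. The elongation factor gene tuf had values of 0.15 (SE 0.24) with shear on MUC5B and 0.32 (SE 0.24) on LDP. celC, whose name pairs it with celB in cellobiose transport, had -0.26 (SE 0.18) and -0.18 (SE 0.19), whereas celB passed on both coatings.

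Consecutively numbered locus tags changed together, a test whose bound was set before its result was seen. Across 1432 pairs of features whose tag numbers differ by 5, the log2 fold changes correlated with r = 0.352 for the coating without shear, 0.301 for the coating with shear, 0.538 for shear on MUC5B and 0.428 for shear on LDP, against 95th percentiles of 0.0429, 0.0421, 0.0430 and 0.0427 in 10000 shuffles. The hypothesis is that tag numbers follow gene order and that neighbouring genes may be transcribed together, which these values fit but which was not tested against an annotation. Runs of at least 3 consecutive tags past the threshold in 1 direction numbered 31 with shear on MUC5B, 13 higher and 18 lower, and 17 with shear on LDP, 5 higher and 12 lower. Without shear the coating comparison had 2 such runs, 1 of them 4 features long and higher on MUC5B with a mean log2 fold change of 1.59, and with shear it had 0 among 76 calls. When the calls were shuffled over the tags 10000 times, a count added after the runs were seen, the 95th percentile was 9 runs with shear on MUC5B, 4 with shear on LDP and 0 in each coating comparison.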
